A study of Mus musculus with 2 samples.

How the data were processed

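The measurements are total RNA-seq of embryonic mouse kidney in 2 libraries, which the labels call biological replicates 1 and 2. Per the labels, RNA over 200 nt was extracted with a mirVana kit, 10 ng entered each library, a manual of a SMARTer Ultra Low kit is among the protocols, and external spike-in RNAs were added. The number of embryos in the pool of replicate 1 is not given in the sources used here. Per the deposited text notes, values refer to assembly mm10 and annotation M4. The aligner, the quantifier, their versions and the strandedness are not given in the sources used here, so genes that overlap on opposite strands are uncertain.

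The authors deposited a gene table and a transcript table per library. The deposited expected counts are estimated counts per gene or transcript that need not be whole, because reads shared by several genes are divided among them. The deposited TPM values are scaled by the authors to length and to the same sum per library over all entries, spike-ins included, and the deposited FPKM values to length and library size. The deposited posterior mean TPM and the deposited lower and upper TPM bounds, treated as a signal that is never negative, come from the same estimates. The deposited percent of each transcript within its gene sums to 100 for expressed genes. The effective length of the longest gene was 99 nt below its length. TPM of genes with a small effective length is unstable: 5459 mouse genes had an effective length under 50 nt.

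The gene tables hold 69691 entries: 43346 mouse genes, 96 spike-ins, 1 phiX genome and 26248 entries named by a bare number, whose identity is not given in the sources used here. Mouse genes alone entered library sizes and tests. Spike-ins took 2.82% of counts in replicate 1 and 2.08% in replicate 2. Names, gene types and coordinates were taken by stable identifier from GENCODE M21 on GRCm38, the assembly that mm10 names. Of the mouse genes 42462 had an identifier there and 884 did not, and gene models of M4 and M21 can differ. The 2 libraries were treated as separate samples because the labels give them as biological replicates.

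A total of 46 gene lists with 400 entries, 16 contrasts between them, the tests and the alternatives were fixed before the data were examined. The lists cover cell types of the kidney, blood cells, neighbouring tissues, Hox paralog groups, processes and RNA classes. Entries matched in 398 cases (391 distinct genes), and Ahsp and Tf were not matched. A gene was called detected at 1 TPM in both libraries. List contrasts are differences of the mean of log2(mean TPM + 0.1) over members, tested by two-sided permutation of genes, exact up to 1000000 assignments and otherwise with 100000 resamples, with Benjamini-Hochberg adjustment. Differences on that scale understate changes of genes near zero. For comparisons of the pools, expected counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 (R 4.3.3), log2 ratios used a prior count of 2, and genes with a mean of at least 1 CPM entered. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept only. List medians were compared with 10000 random lists of equal size, drawn among genes of similar mean expression, as a description of these libraries. DESeq2 1.42.0 size factors and dispersion trend served as alternatives. Tables and tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

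Genes named in the text are, per list, the up to 4 members with the highest and the up to 2 with the lowest mean TPM, all Hox, basement membrane, Y-linked and embryonic globin genes, the 20 entries with the highest mean TPM, the 12 largest ratios in each direction among genes with a mean of at least 5 TPM and at least 50 counts in sum, and up to 10 list genes whose leading transcript differed. Some genes that this rule takes are not reported here. Lung genes and gene families in the closing part were chosen after the data were examined.

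The code was tested on simulated data with 200 changed genes. For the comparison of the pools, 100.0% of 100 genes changed 4-fold were found over 2-fold, 5.1% of 99 genes changed 1.5-fold, and 0.31% of 15145 unchanged genes. A simulated coefficient of variation of 0.15 was recovered as 0.17 over 15344 genes, changed genes included. For list differences, 4.5% of 200 unshifted lists of 10 genes fell outside the band and 74.5% of lists shifted by 0.3 log2 units lay above it (15145 genes). The simulated genes varied independently of each other, which genes of a real list need not do. For list contrasts, 5.5% of 200 pairs of lists without a difference had p under 0.05, and 89.5% of pairs 6 log2 units apart did (391 genes).

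The alternatives covered detection units and thresholds, scaling (DESeq2 size factors, library size, spike-ins), filters on low counts, the unit, the pseudocount, the median in place of the mean (as a value, with the p of the mean), and leaving out each replicate. After the data were examined a correction of ratios for GC content and length, a background of protein-coding genes for the random lists and a restriction to protein-coding genes were added.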

Results

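Total RNA was sequenced from kidneys of B6NCrl mouse embryos at 16.5 days of development, a stage at which nephron progenitors, forming nephrons and maturing tubules are present side by side. The samples form 1 group with 2 biological replicates, each a pool of embryos of both sexes, and the pool of replicate 2 came from 41 embryos. The labels name no second tissue, age or treatment, so the comparisons are between fixed gene lists within this tissue and between the 2 pools. Expected counts summed to 35255968 in replicate 1 and 38706236 in replicate 2, of which 34261328 and 37900132 fell on mouse genes. At these depths 10 counts on a transcript with an effective length of 2 kb came to 0.218 and 0.201 TPM. Of 43346 mouse genes, 15048 reached 1 TPM in both libraries, including 13352 of 21474 protein-coding genes (62.2%). Values are the mean ± SD of both libraries in TPM (n = 2) unless stated. Intervals cover counting error or the draw of genes only, and floors counting error only. The smallest two-sided p that an exact test over 2 paired libraries can give is 0.5.

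The RNAs with the highest TPM in these libraries included the 7SL RNAs of the signal recognition particle, adult globins and mitochondrial messages. How well the library preparation captured each class of RNA was not tested, so these ranks describe the libraries. Rn7s2 and Rn7s1 each stood at 12865 TPM (SD 1968 for both, n = 2), and because the copies are nearly identical their deposited credibility bounds in replicate 1 ran from 2299 to 18020 for Rn7s2. The adult alpha-globin gene Hba-a2 reached 9096 ± 432 TPM and Hba-a1 3590 ± 107, and the beta-globin genes Hbb-bs and Hbb-bt 4967 ± 121 and 2823 ± 62.9. Of the mitochondrial genes, mt-Atp6, a subunit of ATP synthase, led by its estimate with 7191 ± 164 TPM (deposited bounds in replicate 1 from 5054 to 7563), followed by mt-Atp8 with 4908 ± 407. The cytoskeletal gene Actb (5146 ± 126), the ferritin light chain Ftl1 (4476 ± 365), the elongation factor Eef1a1 (4261 ± 142) and the nuclear RNA Malat1 (4069 ± 1268) were also among the 20 highest entries, which comprised 15 mouse genes and 5 spike-ins and took 13.8% ± 0.71 of TPM. Globins together took 2.05% ± 0.06 of TPM, the 13 mitochondrial messages 2.60% ± 0.16, ribosomal proteins 5.34% ± 0.18 and spike-ins 5.48% ± 1.17. Gm28437 (8293 ± 373), Gm10123 (3589 ± 321) and the microRNA gene Gm22133 (4808 ± 219) are uncertain, since the first 2 are pseudogenes, whose reads can be shared with other genes, and Gm22133 has an effective length of 10 nt. The deposited bounds of Gm28437 in replicate 1 ran from 1785 to 8508. Which genes share its reads was not tested, and the levels of such genes depend on how those reads were divided. Of the 2 mitochondrial ribosomal RNAs, mt-Rnr2 stood at 2110 ± 158 TPM and mt-Rnr1 at 771 ± 15.4.

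Markers of the whole nephron lineage were detected, from progenitors to segmented tubules. All 12 nephron progenitor genes passed 1 TPM in both libraries, with a median of 28.3 ± 3.04. Cited1, a transcriptional co-regulator of the cap mesenchyme, led with 127 ± 10.2 TPM, followed by Crym (61.5 ± 2.26), Uncx (54.6 ± 6.61) and the integrin Itga8 (36.6 ± 1.77). Six2, which maintains progenitor self-renewal, stood at 12.1 ± 1.31 and Gdnf, the ligand that draws the ureteric bud, at 6.64 ± 1.07. The 10 genes of early nephrons had a median of 28.5 ± 0.117, led by Pax8 (122 ± 13.2), Osr2 (85 ± 3.01), Cdh6 (49.7 ± 0.926) and the Notch ligand Jag1 (36.2 ± 7.28), with Wnt4 at 7.74 ± 1.51 and Pou3f3 at 6.62 ± 0.311. Podocyte genes, which build the glomerular filter, had a median of 22.1 ± 0.753 over 10 of 10 detected members: Wt1 stood at 110.3 ± 8.38 and Podxl at 65.2 ± 0.983, while Nphs1 (4.71 ± 0.361) and Plce1 (2.58 ± 0.092) were lowest. All 14 proximal tubule genes were detected (median 20.9 ± 2.74), led by the phosphate transporter Slc34a1 with 229 ± 15.9 TPM, Ass1 (122 ± 22.6), Slc27a2 (62.8 ± 7.76) and the water channel Aqp1 (50.1 ± 12.1), with Slc5a12 (3.05 ± 0.028) and Kap (2.71 ± 1.52) lowest. The 7 loop of Henle genes had a median of 8.01 ± 0.665, with the salt transporter Slc12a1 at 60.5 ± 3.92 and Irx1 at 2.21 ± 1.05. Of 8 distal tubule genes 6 were detected (median 7.60 ± 1.89): Tfap2b stood at 48.1 ± 3.58, Tmem52b at 45 ± 1.67 and Wnk4 at 29.1 ± 4.77, whereas Trpm6 (0.64 ± 0.071) and Pvalb (0.185 ± 0.262) stayed below 1 TPM.

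Marker lists of the segments were compared in level, on the mean of log2(TPM + 0.1). The test was a two-sided permutation of genes between the lists, exact where the assignments allowed, with Benjamini-Hochberg adjustment over 16 contrasts. Each list holds different genes, so a difference between lists does not measure the amount of a segment. Early nephron genes differed from progenitor genes by -0.06 log2 units (adjusted p = 0.92), podocyte genes by -0.52 (adjusted p = 0.57) and proximal tubule genes by -0.28 (adjusted p = 0.74), none of which passed the test. Podocyte genes differed from proximal tubule genes by -0.24 (adjusted p = 0.79). Loop of Henle genes differed from proximal tubule genes by -1.12 (exact permutation test, p = 0.18, adjusted p = 0.29) and distal tubule genes by -1.84 (p = 0.072, adjusted p = 0.13), which did not pass. In all, 6 of 16 contrasts passed, and genes of a list are not independent replicates. Pairs of lists with a difference were simulated only at 6 log2 units, so contrasts that did not pass do not show equal levels.

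Markers of both the growing ureteric tips and the differentiated collecting duct were detected. All 8 tip genes were detected (median 25.9 ± 1.12), led by Gfra1 (58.8 ± 3.31), the transcription factors Etv5 (51.7 ± 1.84) and Etv4 (47.3 ± 6.24) and the branching ligand Wnt11 (26.7 ± 0.969), with Slco4c1 at 6.32 ± 0.007 and Sox8 at 3.81 ± 0.976. All 12 collecting duct genes were detected (median 32.9 ± 1.01): the calcium-binding protein Calb1 stood at 135 ± 5.64, the vasopressin-regulated water channel Aqp2 at 112 ± 31.1, Gata3 at 91.2 ± 6.95 and the sodium channel subunit Scnn1b at 47.1 ± 3.29, with Aqp4 (4.24 ± 0.304) and Elf5 (3 ± 0.53) lowest. Tip and duct lists differed by -0.43 (exact permutation test, adjusted p = 0.71). The 6 genes of intercalated cells were lower, with a median of 5.92 ± 0.856, led by Foxi1 (22.1 ± 1.39), Atp6v1b1 (9.12 ± 1.39), Atp6v0d2 (7.34 ± 0.636) and Atp6v1g3 (4.51 ± 1.07), with Slc26a4 at 1.33 ± 0. They were lower than collecting duct genes (log2 difference -2.30, exact permutation test, p = 0.016, adjusted p = 0.042; -2.36 and -2.25 in replicates 1 and 2). That call was lost in replicate 2 alone (adjusted p = 0.052) and with only members of at least 1 TPM in both libraries (adjusted p = 0.095), while over the alternatives tried the adjusted p ranged from 0.029 to 0.095. Urothelial genes, which line the ureter and pelvis, were detected for 6 of 7 members (median 5.81 ± 3.20), from Upk3a (57.9 ± 6.21) and Upk1b (14.8 ± 7.11) to Trp63 (1.14 ± 0.177) and Krt5 (0.39 ± 0.255).

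Stromal, mural and vascular genes were among the highest markers. The 7 cortical stroma genes had a median of 59.1 ± 3.82, led by Tcf21 (301 ± 13.9), the retinoic acid synthase Aldh1a2 (274 ± 8.24), and Meis1 (104 ± 0.042), while Foxd1, the classical marker of stromal progenitors, stood at 4.19 ± 0.41. Their difference from progenitor genes was 0.53 (exact permutation test, adjusted p = 0.71). The 6 medullary stroma genes (median 32.7 ± 2.31) included the opioid precursor Penk at 395 ± 18.2, Cldn11 at 93 ± 6.25 and Lef1 at 20.1 ± 3.45. Renin and mural genes (10 of 10, median 43.4 ± 5.99) were led by the smooth muscle actin Acta2 (434 ± 183), renin itself, Ren1 (375 ± 52), Tagln (80.8 ± 36.5) and Pdgfrb (55.2 ± 0.092), with Cspg4 at 16.3 ± 0.615 and Myocd at 5.01 ± 1.96. All 12 endothelial genes were detected (median 36.5 ± 1.55), led by Egfl7 (218 ± 9.09), Plvap (135 ± 2.24), Emcn (82.8 ± 0.75) and Pecam1 (62.3 ± 0.771). They stood 2.22 log2 units above macrophage genes (permutation test, p = 0.0002, adjusted p = 0.001; 2.22 and 2.23 in the 2 libraries). Macrophage genes were nevertheless all detected (12 of 12, median 11.9 ± 0.120), with the complement genes C1qb (35 ± 1.86) and C1qa (20.0 ± 2.94), Fcer1g (29.9 ± 1.8) and Tyrobp (25.2 ± 0.7) highest. Only 1 of 8 lymphocyte genes passed 1 TPM, Cd79a at 1.6 ± 0.092, and the list was lower than macrophage genes (log2 difference -5.36, exact permutation test, p = 1.6e-05, adjusted p = 0.00013; -5.41 and -5.45 in the 2 libraries). With members of at least 1 TPM only, Cd79a alone was left (difference -2.51, exact adjusted p = 0.35, range over the alternatives 0.00013 to 0.35), and 1 gene against 12 cannot give an exact p under 0.077. Ms4a1 had a count of 0 in both libraries, which allows up to 3 counts in each. The size of the lymphocyte difference depended on the pseudocount, with -3.18 at 1 and -6.57 at 0.01. Among the 10 matched erythroid genes 9 were detected, and beyond the globins Alas2, the first enzyme of haem synthesis in red cells, stood at 65.9 ± 4.45, with Klf1 at 2.17 ± 0.191 and Gata1 at 0.525 ± 0.078. The embryonic globins were low beside the adult ones: Hbb-y stood at 42.3 ± 2.94, Hba-x at 18.2 ± 1.92 and Hbb-bh1 at 1.15 ± 0.523.

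Genes of neighbouring tissues were detected unevenly. Of 9 adrenal cortex genes 8 passed 1 TPM in both libraries (median 13.6 ± 5.18), led by the steroid enzymes Cyp21a1 (33.4 ± 2.78), Cyp11a1 (29.5 ± 12.7), Hsd3b1 (25.4 ± 11.5) and Cyp11b1 (22.2 ± 5.58), with Nr5a1 at 2.58 ± 1.05 and Cyp11b2 at 1 ± 0.841. The list differed from progenitor genes by -1.59 (exact permutation test, p = 0.023, adjusted p = 0.053), which did not pass; in replicate 1 alone it did, with -2.09 (adjusted p = 0.011, range over the alternatives 0.011 to 0.21). All 6 chromaffin genes of the adrenal medulla were detected (median 6.93 ± 3.72), led by Slc18a1 (13.9 ± 0.509), Th (8.48 ± 4.24) and Chga (7.83 ± 4.71), with Pnmt at 2.18 ± 0.127. Of 8 gonad genes only Insl3 passed, at 3.77 ± 3.8, and the list was lower than progenitor genes (log2 difference -6.63, exact permutation test, p = 7.9e-06, adjusted p = 0.00013; -7.16 and -6.33 in the 2 libraries). With members of at least 1 TPM only, Insl3 alone was left (difference -2.81, exact adjusted p = 0.21, range over the alternatives 0.00013 to 0.21), where the smallest exact p is again 0.077. Foxl2 and Dmrt1 had a count of 0 in both libraries. The size of the gonad difference depended on the pseudocount, with -4.4 at 1 and -8.04 at 0.01. Because the lists were chosen by tissue, its direction follows largely from that choice. All 9 matched liver genes were detected (median 12.9 ± 2.45), with alpha-fetoprotein, Afp, at 105 ± 12.3, Apoa2 at 22.6 ± 6.08 and albumin, Alb, at 15 ± 3.22. Skeletal muscle genes passed in 7 of 8 cases (median 8.55 ± 1.2; Acta1 93.5 ± 63.9, Mylpf 21.8 ± 0.898, Myod1 0.63 ± 0.085). Nerve and glia genes passed in 6 of 10 (median 3.59 ± 0.873; Stmn2 11.7 ± 3.4, Elavl4 10.9 ± 2.74, S100b 0.41 ± 0.042). Cartilage genes passed in 2 of 5 cases (Col2a1 16.1 ± 0.948, Col9a1 7.07 ± 0.177). The 3 mesothelial genes had a median of 4.72 ± 0.679 (Upk3b 6.14 ± 2.35, Msln 4.72 ± 0.679). Gut and pancreas genes passed in 1 of 6 cases, Cpa1 at 1.74 ± 0.417, and none of 4 adipose genes did, with Cidea highest at 0.2 ± 0.071. Across the kidney lists, chosen as markers of its cell types, 97.7% of members were detected, against 61.8% across the neighbouring-tissue lists. The latter share was close to the 62.2% of all protein-coding genes.

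**Figure D1:**
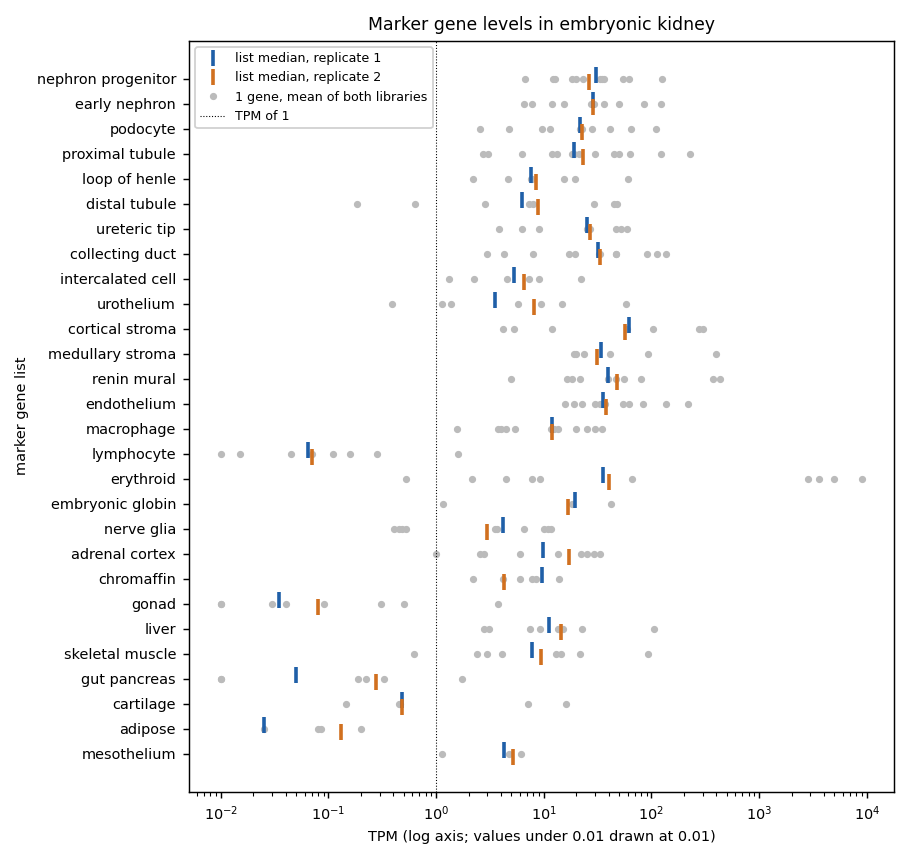
TPM (log axis) of each marker gene as the mean of both libraries (grey points), by list, with the list median in replicate 1 (blue) and replicate 2 (orange); the dotted line is 1 TPM. Cortical stroma has the highest median of the kidney lists (61.8 and 56.4 TPM), while lymphocyte, gonad, gut and pancreas, cartilage and adipose medians lie below 1 TPM in both libraries.

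Hox transcripts differed in level between paralog groups. The 10 genes of paralog groups 9 to 11, which pattern the metanephric kidney, were all detected (median 27.2 ± 2.02), led by Hoxa10 (125 ± 1.7), Hoxa9 (47.4 ± 0.679), Hoxc10 (42.7 ± 2.18), Hoxd9 (31.7 ± 0.686) and Hoxd10 (29.8 ± 2.38). Next came Hoxa11 (24.8 ± 1.83), Hoxb9 (19.1 ± 1.39), Hoxd11 (13.2 ± 2.15), Hoxc9 (6.89 ± 0.948) and Hoxc11 (1.16 ± 0.163). Of groups 12 and 13 only Hoxd12 passed 1 TPM (3.85 ± 0.042); Hoxd13 stood at 0.25 ± 0.071, Hoxa13 at 0.13 ± 0, Hoxc13 had 1 count in replicate 1, and Hoxb13 and Hoxc12 had none. Groups 9 to 11 lay 6.27 log2 units above groups 12 and 13 (exact permutation test, p = 0.00025, adjusted p = 0.001; 6.36 and 6.19 in the 2 libraries) and 2.81 above groups 1 to 4 (exact permutation test, p = 0.0029, adjusted p = 0.0092; 2.86 and 2.77). The distance to groups 12 and 13 depended on the pseudocount, with 4.03 at 1 and 7.97 at 0.01. With members of at least 1 TPM only, the difference from groups 1 to 4 was 1.97 over 10 and 9 genes (exact p = 0.018, adjusted p = 0.095, range over the alternatives 0.0067 to 0.095). Of groups 12 and 13 that filter left Hoxd12 alone (difference 2.38, exact adjusted p = 0.48, range 0.001 to 0.48), and 1 gene against 10 cannot give an exact p under 0.091. All 11 genes of groups 5 to 8 were detected (median 9.34 ± 1.86), with Hoxb7, a gene active in the ureteric bud, at 53.6 ± 3.37, Hoxb6 at 44 ± 2.35, Hoxd8 at 35.9 ± 3.31, Hoxa7 at 24.9 ± 1.2 and Hoxb5 at 18 ± 2.69. Hoxb8, Hoxc6, Hoxa5, Hoxc8, Hoxc5 and Hoxa6 lay between 9.34 ± 1.86 and 2.79 ± 0.509. Groups 1 to 4 (9 of 12, median 3.45 ± 0.216) ran from Hoxb2 (29.3 ± 1.5), Hoxd3 (12.5 ± 0.693) and Hoxa3 (7.85 ± 1.36) through Hoxc4, Hoxb4, Hoxd4, Hoxb3, Hoxa2 and Hoxa4 (1.11 ± 0.141) to Hoxd1 (0.83 ± 0.014) and Hoxb1 (0.085 ± 0.021).

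**Figure D2:**
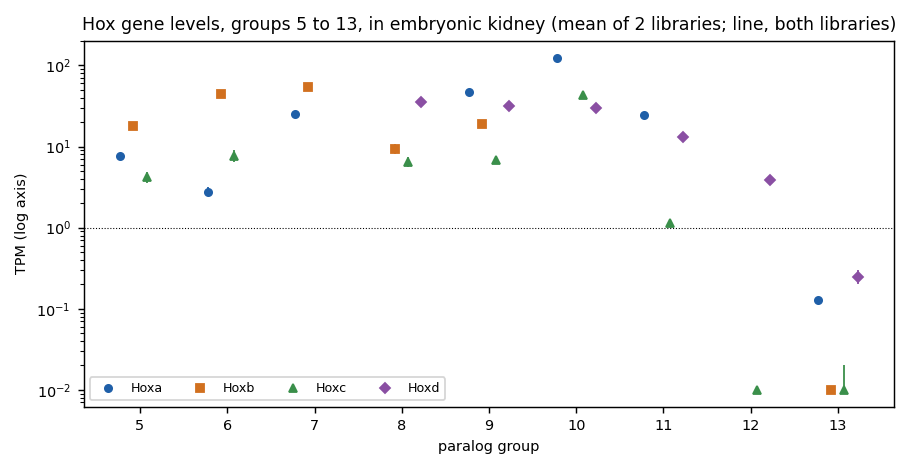
TPM (log axis) of each Hox gene of paralog groups 5 to 13, by group, with a symbol per cluster at the mean of both libraries and a line spanning the 2 libraries; values under 0.01 are drawn at 0.01 and the dotted line is 1 TPM. Hoxa10 is highest (125 TPM) and of groups 12 and 13 only Hoxd12 lies above 1 TPM (3.85 TPM).

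Basement membrane genes of the early and the mature kidney were both transcribed. The early set comprised Col4a1 (267 ± 20.6), Lamb1 (152 ± 2.19), Col4a2 (103 ± 4.53) and Lama1 (23.9 ± 0.728), and the mature set Lamb2 (59 ± 4.08), Lama5 (46 ± 3.35), Col4a5 (21.1 ± 0.636), Col4a4 (3.77 ± 0.431) and Col4a3 (3.69 ± 0.488). The early genes were 2.71 log2 units higher, which did not pass over 4 and 5 genes (exact permutation test, p = 0.071, adjusted p = 0.13). Branching signals were detected for 13 of 14 genes (median 8.46 ± 0.513), from the receptor Fgfr2 (105 ± 5.82) and Bmp7 (37 ± 5.16) to Fgf7 (1.25 ± 0.191) and Grem1 (0.155 ± 0.007). All 10 genes linked to cystic kidney disease were detected (median 13.4 ± 0.244), with Glis2 at 39.9 ± 5.2, Bicc1 at 38.3 ± 2.59 and Pkhd1 at 5.11 ± 1.69. Imprinted genes were high (19 of 19, median 85.2 ± 12.8): Mest reached 1851 ± 46.9, Igf2 454 ± 32, Cdkn1c 418 ± 46.8 and H19 348 ± 27.8. All 16 proliferation genes were detected with a median of 153 ± 1.71, led by Cdk1 (411 ± 45.3) and Birc5 (241 ± 3.98). Hypoxia genes (11 of 11, median 39.2 ± 0.700) ranged from Ldha (1552 ± 113) to Car9 (1.75 ± 0.672). Immediate early genes (9 of 10, median 12.2 ± 0.488) ranged from Ier2 (62.9 ± 3.77) and Jun (60.1 ± 0.424) to Fosb (0.115 ± 0.064), and linker histones (4 of 5, median 14.6 ± 0.0212) from Hist1h1e (33.3 ± 0.354) to Hist1h1a (0.99 ± 0.382). Among small structured RNAs 5 of 9 were detected, with Rn7sk at 210.2 ± 14.8 and Rpph1, the RNA of RNase P, at 96.3 ± 33.4; these short genes sit close to the size limit of the libraries. Of the nuclear long non-coding RNAs 6 of 7 were detected, with Xist at 25 ± 5.75, Neat1 at 23.1 ± 0.205 and Miat at 0.4 ± 0.099.

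The 2 pools agreed closely for most genes and differed for a small set. Among 15363 genes with a mean of at least 1 CPM, the median absolute log2 ratio after TMM scaling was 0.112, a 1.08-fold difference, against 0.043 from counting noise alone. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.986 and Spearman's rho 0.9925. The ratio exceeded 2-fold for 361 genes (2.35%), 89 higher and 272 lower in replicate 2, where counting noise alone gave 1.1. Of the 272 lower genes 180 were processed pseudogenes, whose median log2 ratio was -0.97 over 369 genes, against 0.01 over 13902 protein-coding genes. With protein-coding genes only, a choice made after the data were examined, 129 genes exceeded 2-fold, 84 of them higher and 45 lower. Scaling by the spike-ins, which moved the median of all genes by 0.43, gave 320 higher and 151 lower. The biological coefficient of variation was 12.6%, and 9.4% over protein-coding genes. With 1 library per pool a difference between the pools has no test, so values only are given.

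Genes of several cell types and tissues differed together between the pools. Of 38 lists with at least 3 measured members, the median ratio of 21 fell outside the central 95% of 10000 random lists of equal size matched on mean expression, 10 above and 11 below. For lists of genes that vary independently, 1.9 are given by chance. Genes of 1 cell type or process can vary together, which widens the spread of their medians, so the 21 are a description and not a test. Ratios are relative to the median of all genes. Proximal tubule genes were higher in replicate 2 in 13 of 13 cases (median log2 ratio 0.27, random band -0.07 to 0.09), with Slc34a1 at 218 and 239.9 TPM in replicates 1 and 2 and Aqp1 at 41.6 and 58.7. Nephron progenitor genes were lower in 10 of 12 cases (median -0.18, band -0.09 to 0.09), with Cited1 at 134 and 119 and Gdnf at 7.4 and 5.88. Early nephron (median 0.04), podocyte (0.09), loop of Henle (0.12), distal tubule (0.07), ureteric tip (-0.07), intercalated (0.10), cortical stroma (-0.08) and endothelial (0.02) medians stayed inside their bands. The same held for macrophage (0.11), erythroid (-0.07), Hox groups 5 to 8 (-0.17), both basement membrane lists (0.07 early and 0.13 mature), branching signals (-0.10), proliferation (0.01), hypoxia (0.07) and linker histones (-0.02). Hox groups 5 to 8 left the band on the TPM scale (-0.30), after correction for GC content and length (-0.20) and against protein-coding genes (-0.17). So did early basement membrane after that correction (0.14), distal tubule without a filter on low counts (0.18) and cortical stroma on the TPM scale (-0.13). Collecting duct genes lay just above the band (median 0.11, band -0.09 to 0.10), and not above it on the TPM scale (0.05) or, added after the data were examined, corrected for GC content and length (0.09). Medullary stroma (-0.14), Hox groups 9 to 11 (-0.16, 9 of 10 lower), Hox groups 1 to 4 (-0.27, 5 of 9 lower), cyst genes (-0.17), imprinted genes (-0.11), nuclear long non-coding RNAs (-0.38) and mitochondrial messages (-0.22, 11 of 13 lower) lay below their bands. Under spike-in scaling the medians of these 7 lists and of the progenitor list were positive, since all genes shifted by 0.43; they stayed below their shifted bands. For Hox groups 1 to 4 the median was 0.02 without a filter on low counts and -0.17 on the TPM scale, both inside the band.

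Further lists outside their bands concerned tissues next to the kidney, its outflow, mural cells, 2 other gene sets and the Y-linked genes. Urothelial genes were higher in replicate 2 in 6 of 6 cases (median log2 ratio 0.49), with Upk1b at 9.81 and 19.9 TPM and Upk2 at 3.55 and 8.08. Renin and mural genes were higher in 9 of 10 (0.32), with Acta2 at 305 and 564 and Tagln at 55 and 107 but Ren1 at 338 and 411, Pdgfrb at 55.1 and 55.2 and Cspg4 at 15.9 and 16.8. Adrenal cortex genes were higher in 8 of 9 (0.82): Cyp11a1 stood at 20.6 and 38.5 and Hsd3b1 at 17.3 and 33.5. Chromaffin genes moved the other way and were lower in 6 of 6 (-1.01), with Th at 11.5 and 5.49 and Chga at 11.2 and 4.5 but Slc18a1 at 14.3 and 13.6 and Pnmt at 2.27 and 2.09. Nerve and glia genes were lower in 6 of 6 (-0.50), with Stmn2 at 14.1 and 9.25; without a filter on low counts the nerve and glia median was -0.20, inside the band. Liver genes were higher in 9 of 9 (0.42), with Afp at 96.7 and 114 and Alb at 12.7 and 17.2. Skeletal muscle genes were higher in 6 of 7 (0.37), with Acta1 at 48.3 and 139, and mesothelial genes in 3 of 3 (0.79), with Upk3b at 4.48 and 7.8. Small structured RNAs (0.30, 4 of 4) and immediate early genes (0.11, 7 of 9) also lay above their bands, the latter not on the TPM scale (0.12), after correction for GC content and length (0.04) or against protein-coding genes (0.11). The 4 Y-linked genes were lower in 4 of 4 cases (-0.80): Eif2s3y stood at 25.9 and 16.3 TPM, Ddx3y at 22.5 and 12.4, Uty at 11.8 and 6.65 and Kdm5d at 9.53 and 5.41, while Xist, expressed from the inactive X chromosome, stood at 20.9 and 29.1. Under spike-in scaling the medians of the chromaffin (-0.58), nerve and glia (-0.07) and Y-linked lists (-0.37) stayed negative. Lists with fewer than 3 measured members have values only: Insl3 of the gonad list stood at 1.08 and 6.46 TPM and Cd79a at 1.67 and 1.54, and the medians of the embryonic globins (-0.24), cartilage genes (0.04) and mitochondrial ribosomal RNAs (-0.07) rest on 2 genes each.

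**Figure D3:**
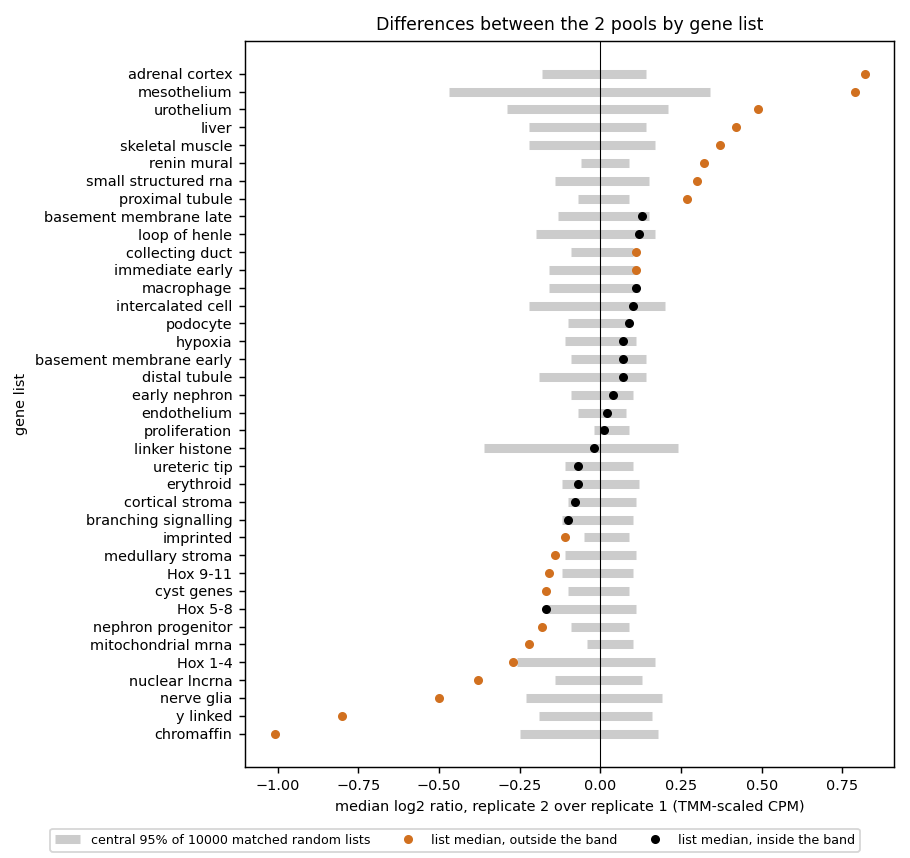
Median log2 ratio of replicate 2 over replicate 1 (TMM-scaled CPM) for each of 38 gene lists; grey bars span the central 95% of 10000 random lists matched on size and expression, orange points lie outside and black points inside. Adrenal cortex is highest (0.82) and chromaffin lowest (-1.01); under spike-in scaling all genes shift by 0.43, and of the 11 medians below their bands 8 turn positive.

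The genes that differed most between the pools were led by Sftpc, which encodes the lung surfactant protein C. It had 8 counts in replicate 1 and 3959 in replicate 2 (0.49 and 225 TPM; identifier ENSMUSG00000022097.3; GRCm38 chromosome 14, 70520949 to 70524081). Other lung genes, looked up after that value was seen, had 2 and 149 counts (Sftpb) and 2 and 289 counts (Cldn18) in replicates 1 and 2. Among the 12 highest ratios, the smooth muscle actin Actg2 was 8.7-fold higher in replicate 2 (17.4 and 153 TPM; chromosome 6, 83512905 to 83536265), Tnnt2 3.94-fold (chromosome 1, 135836354 to 135852260) and Cnn1 3.83-fold (chromosome 9, 22099216 to 22109630). Alyref (3.95-fold), Btbd2 (3.6), Id4 (3.58), Tmed7 (3.52), Mogs (3.48) and Csnk1g2 (3.44) were the other protein-coding genes among them, with Btbd2 (chromosome 10, 80642617 to 80657071) and Csnk1g2 (chromosome 10, 80622838 to 80640749) next to each other. Gm13370 and an entry with the identifier ENSMUSG00000090407.1, whose ratios came next after that of Sftpc, stood at 0 and 21.1 and 0.12 and 21.7 TPM in replicates 1 and 2, with wide deposited bounds. Of the 12 genes with the largest ratios in the other direction most are pseudogenes, whose counts can include reads shared with parent genes. Gm10233 and Rpl21-ps15 had 0 counts in replicate 2, and the identifier ENSMUSG00000090234.1 had 0.51. Gm8762 (10.2-fold lower in replicate 2), Gm6344 (8.61), Tmem254a (7.4), Gm12854 (7.17), Gm6682 (6.37), Gm16379 (6.1), Rpl9-ps4 (5.95), Gm6485 (5.9) and Cox6c2 (5.74) followed.

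Spike-in RNAs, added from outside to each sample, were compared between the libraries in the same way. After centring on their own median, 52 spike-ins had a median absolute log2 ratio of 0.130, and mouse genes matched on count level had 0.123. Of the 52, 0 exceeded 2-fold. The coefficient of variation was 6.6% for spike-ins and 12.6% for mouse genes, but these 2 sets were not matched on count level. For mouse genes with a mean of at least 10 CPM it was 9.3%. In the matched comparison of ratios above, mouse genes had no larger spread than spike-ins. Spike-in counts per mouse-gene count in replicate 2 were 0.73 times those in replicate 1.

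The leading transcript of a gene was compared between the libraries. Of 8237 genes with several transcripts and at least 5 TPM in both libraries, 93.5% had the same leading transcript in both (exact Clopper-Pearson 95% interval 92.9 to 94.0). That interval treats genes as independent draws and holds no error of the transcript estimates or between pools. Where the leading share was under 60% in both libraries, 82.2% of 2755 genes did. Among 166 genes of the fixed lists 10 differed. For Spry1, an inhibitor of branching signals, Spry1-203 held 63.8% in replicate 1 and 35.6% in replicate 2, where Spry1-201 held 63.2%. For Wnt11 the leading transcript differed, with Wnt11-202 at 51.1% and 37.3% in replicates 1 and 2 and Wnt11-205 at 33.7% and 45.5%. H19, Lama5, Sox17, Synpo, Hoxb8, Hoxa3 and Kdm5d were among the others, with leading shares of at most 53.6%.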

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

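The tests on the Y-linked and X-linked genes, on the Sftpc locus alone and on GC content and length were chosen after the result was seen, and the second set of lung genes and the interval of the retained-intron ratio were chosen after the first outcome.

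Entries named by a bare number, which no comparison used, held 55.3 expected counts in replicate 1 and 46.7 in replicate 2, above the 3 counts that a count of 0 allows. The counts fell on 8 entries in each library.

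Sftpc had 8 counts in replicate 1 and 3959 in replicate 2, and lung genes looked up afterwards went with it: Sftpb had 2 and 149 counts, Cldn18 2 and 289, Sftpa1 0 and 98, Nkx2-1 0 and 68 and Lamp3 6 and 35.5. An artefact at the Sftpc locus alone is argued against by these 5 of 5 genes at other loci, all over 2-fold higher. Correction for GC content and length left the median log2 ratio of the 6 genes at 5.32, from 5.36, with only the 4 that passed the filter corrected. Ratios followed GC content and length weakly across all genes (Spearman's rho 0.124 and -0.149), so that correction had little room to move them. A bias of that kind was small for genes at large, and for the lung genes by themselves this test decides nothing. RNA from lung may be present in the library of replicate 2, but its first test missed its prediction: 5 of 6 lung genes not yet looked at were higher, yet their summed CPM was 1.15 times that of replicate 1, under the bound of 1.2 written beforehand as arguing against it. That bound was judged unsuited after its outcome, because Rtkn2, Cftr and Aqp5 reached 2 TPM in replicate 1 and held 96.0% of its summed counts, and a second set of 4 lung genes, written before its values were seen, came to 2.82 times (143 and 446 counts, 4 of 4 higher, Scgb3a2 at 0 and 81). In this set too 1 gene held most counts: Lgi3, at 1.85 TPM in replicate 1, had 131 and 286. Cxcl15 had 2 and 26 counts and Tbx5 10 and 53. Of the 12 genes of the first list 4 passed 1 TPM in replicate 1 and 0 stand on the fixed lists; whether lung tissue entered the pool or RNA of another library entered later was not tested, and no biological explanation was tested.

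Processed pseudogenes were lower in replicate 2, with a median log2 ratio of -0.97 over 369 genes and 330 of them lower. Genomic DNA in replicate 1 is argued against: olfactory receptor genes, 1050 in number, had 134.2 and 175.0 counts, a CPM ratio of 0.85 for replicate 1 over replicate 2 (exact Clopper-Pearson 95% interval 0.67 to 1.07). For a higher share of unspliced RNA in replicate 1, retained-intron transcripts took 5.70% and 5.14% of TPM. The ratio of 1.11 (1.09 to 1.13 over 1000 resamples of genes) lay under the bound of 1.2 written beforehand as arguing against it. That test cannot decide the question, because the class does not measure unspliced RNA alone. It includes the leading transcripts of the abundant globin genes Hbb-bs and Hba-a1, with 55.1% and 80.7% of their genes in replicate 1. Nuclear long non-coding RNAs (median -0.38) and lincRNAs (-0.21, 172 of 239 lower) were lower in replicate 2 as well, and a share of nuclear RNA as such was not tested. Reads shared with parent genes, and divided differently in each library, may account for the pattern: 358 pseudogenes with fractional counts had a median of -1.0, while only 11 with whole counts in both libraries (within 0.005), with a median of 0.04 and 5 of them lower, were left for the test. What made the division differ, and why 139 of 150 genes of the annotation type TEC were also lower (median -0.51), stays open, and no biological explanation was tested.

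Y-linked genes were lower in replicate 2, with a median log2 ratio of -0.80 (range -0.87 to -0.69). After correction for GC content and length the median was -0.71. Ratios followed GC content and length only weakly across all genes, so that correction had little room to move the median. For the Y-linked genes by themselves this test decides nothing. A lower share of male embryos in the pool of replicate 2 may account for the lower Y-linked levels but stays open. Xist had a log2 ratio of 0.46 in the other direction, a value seen before the test. The median of -0.03 over 531 other X-linked genes would lie near 0 with or without such a share. The labels give the sex of the pools as mixed without shares, so the hypothesis was not set against a count of embryos.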

How the results depend on the processing

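Of the alternatives, the restriction to protein-coding genes, the background of protein-coding genes and the correction for GC content and length were chosen after the data were examined. No paired analysis was possible because there is only 1 group. For the main results, 259 values under alternatives stayed on their side of the threshold or within the range allowed for them. Of the others, 10 left that range, 9 list medians outside their bands changed sign, 13 no longer passed and 1 newly passed. Among the 259, contrasts that did not pass changed sign in 3 cases: early nephron against progenitor with the median in place of the mean (0.03) and without replicate 1 (0.05), and podocyte against proximal tubule with the median (0.14). The number of detected genes stayed between 11346 and 18476. Of the 361 genes over 2-fold 297 had a mean of 1 to 10 CPM and 64 a mean of at least 10 CPM. Without a filter 2522 genes exceeded 2-fold, and with protein-coding genes only 129. Counting noise is larger for low genes, so these counts do not show which levels carry the difference between the pools. The median absolute log2 ratio was 0.189 without a filter and 0.439 under spike-in scaling, and the coefficient of variation under spike-in scaling 0.247, because that scaling shifts all genes. Of the 11 list medians below their bands, the same scaling turned 8 positive: nephron progenitor 0.25, medullary stroma 0.29, Hox groups 1 to 4 0.16, Hox groups 9 to 11 0.27, cyst genes 0.26, imprinted genes 0.32, nuclear long non-coding RNAs 0.05 and mitochondrial messages 0.21. Without a filter on low counts Hox groups 1 to 4 came to 0.02 and nerve and glia to -0.20, inside their bands; the cause was not tested. On the TPM scale collecting duct (0.05), Hox groups 1 to 4 (-0.17) and immediate early genes (0.12) were inside; corrected for GC content and length collecting duct (0.09) and immediate early genes (0.04), and with a background of protein-coding genes immediate early genes (0.11); the cause was not tested. Among list contrasts, keeping members of at least 1 TPM left 1 gene in a list for Hox 9 to 11 against 12 and 13 (2.38), gonad against progenitor (-2.81) and lymphocyte against macrophage (-2.51), so that these could not pass whatever their values. With that filter Hox 9 to 11 against 1 to 4 (1.97, 9 of 12 genes left; the cause was not tested) and intercalated against collecting duct (-2.30, the same members and exact p, with a higher adjusted p from the other contrasts) did not pass either. Leaving out each replicate in turn, intercalated against collecting duct ranged from -2.36 to -2.25 and was lost without replicate 1, and adrenal cortex against progenitor ranged from -2.09 to -1.22 and passed without replicate 2. The 20 highest entries took 6.9% when chosen and measured by expected counts. The share of genes with the same leading transcript was 91.5% at 1 TPM, 94.9% at 20 TPM and 99.1% where a leading share reached 60%. Depth limits the lowest genes in part: counting noise alone gave a median absolute log2 ratio of 0.122 at 1 to 10 CPM, where 0.235 was measured, and 0.016 at 100 CPM or more, where 0.071 was measured.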

Other observations

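The families below and their members were chosen by name after the data were examined, and values are mean ± SD in TPM (n = 2).

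Of 19 Wnt ligands 9 passed 1 TPM in both libraries, led by Wnt11 (26.7 ± 0.969), Wnt5a (22.3 ± 0.75) and Wnt7b (17.1 ± 1.07). Of 22 Fgf ligands 10 passed, with Fgf8 (11.8 ± 1.69) and Fgf1 (9.34 ± 1.36) highest, and of 9 Pax factors 2, Pax8 (122 ± 13.2) and Pax2 (23.6 ± 5.13), of which Pax8 held 83.6% of the family's TPM. Among 12 Bmp genes 8 passed, led by Bmp1 (40.3 ± 0.983), a procollagen protease, and Bmp7 (37 ± 5.16). Of 19 Sox factors 11 passed, with Sox11 (53.3 ± 3.95) and the endothelial factor Sox18 (52.6 ± 3) highest, and of 44 Fox factors 23, with Foxn3 (48.7 ± 1.53) highest.

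Of 33 claudins 17 passed, and Cldn6 (195 ± 8.28) and Cldn7 (189 ± 1.97) stood above Cldn8 (117 ± 3.89), the endothelial Cldn5 and Cldn11 (93 ± 6.25), while 10 had no count. Cadherins passed in 11 of 23 cases, with the kidney-specific Cdh16 at 231 ± 20.5, Cdh11 at 139 ± 7.5 and E-cadherin, Cdh1, at 88.2 ± 3.6. Of 25 Slc22 transporters 17 passed, led by Slc22a6 (44.5 ± 6.98) and Slc22a17 (30.2 ± 2.7), with the urate transporter Slc22a12 at 22.9 ± 0.262. Aquaporins passed in 7 of 12 cases, and after Aqp2, Aqp1 and Aqp3 (46.5 ± 1.73) came Aqp11 (21.1 ± 0). Ephrins and Eph receptors passed in 18 of 22 cases, led by Efna1 (69.9 ± 4.07), and ADAMTS proteases in 17 of 19, where Adamts1 (99.9 ± 7.08) held 41.9% of the family's TPM.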
